A study of Arabidopsis thaliana with 12 samples.

How the data were processed

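Transcripts were measured on 12 arrays of a single Arabidopsis array type, with 3 biological replicates in each of 4 groups: ethanol at 1 h, oligomycin at 1 h, ethanol at 4 h and oligomycin at 4 h. The labels named RMA in the submitters' processing notes, with its version not given in the sources used here. The deposited values were linear array intensity per probe set, between 0 and 6149.7, with 166 zeros, and the 2% trimmed mean lay near 100 in all 12 arrays. RMA commonly gives log2 values without zeros and does not scale arrays to a common trimmed mean, so these values did not have the form of the named method, and the method that made them is not known here. The design had assumed log2 values, which the table did not hold, so the values were turned into log2(intensity + 16) before any test. The added 16 was chosen after the table had been read, from the spread within groups.

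The table held 22810 probe sets, of which 64 control probe sets were left out of the tests and 22746 were tested. Gene names came from the probe set table supplied with the series and from a gene table of the assembly TAIR10.1, used for names only. Of the 14016 tested probe sets named there, 13513 had 1 gene and 503 had several, and the 13513 covered 13356 genes, while 9233 tested probe sets had no single gene name here. In all, 1061 tested probe sets ended in _s_at or _x_at and can detect more than 1 transcript. For gene lists the probe set with the highest mean stood for its gene.

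Limma 3.58.1 in R 4.3.3 fitted the mean of each of the 4 groups to every probe set, with moderated two-sided tests (8 residual and 4.14 prior degrees of freedom). The contrasts were oligomycin against ethanol at 1 h, the same at 4 h, the difference between these effects (the interaction) and 4 h against 1 h in ethanol. P values were adjusted by Benjamini-Hochberg over all probe sets of a contrast, and 0.05 was the threshold. Lists were tested with camera at a preset correlation of 0.01, and with an estimated correlation and fry as alternatives, with adjustment over the 25 lists that had at least 3 measured genes. Calls of members were also made with adjustment over the list alone. The contrasts, tests, thresholds, lists and most alternatives were chosen before the data were examined.

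Of 32 lists with 707 members written from general knowledge, 4 members were left out because the gene tables gave their symbol to another locus and 200 were measured by a single-gene probe set. The lists for nitrate and for seed storage had no measured member, and those for jasmonate, salicylate, antioxidants, the clock and glucosinolates had fewer than 3. Members of the organelle genomes were matched by chromosome or symbol once the gene table had been read. Named genes were, for each effect of oligomycin, the 10 largest called rises and falls at 1 h and 4 h and the 5 largest of the interaction, and up to 3 called members per list, all with a single gene.

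The limma contrasts, and camera at the preset correlation, were tried on simulated data with known changes placed on the groups. Fry, the estimated correlation and the permutation tests were not. Only 66 or 67 probe sets changed at each size, a far smaller share than was called at 4 h or for the interaction. Noise was independent between probe sets. The recovered shares therefore describe that setting and not the real data. Log2 changes of 0.5, 1 and 2 were recovered in 23.9%, 91.0% and 98.5% of probe sets at 1 h, in 31.3%, 82.1% and 100% at 4 h, and in 7.46%, 67.2% and 100% for the interaction, and for time in ethanol in 40.3%, 91.0% and 100%. Among 22546 unchanged probe sets there were 10, 4, 3 and 13 calls. Correlations between arrays of a group were 0.975 to 0.993, and the first principal component held 67.5% of the variance. The lowest were those of the second ethanol replicate of 1 h, 0.975 and 0.979, while the other arrays of its group correlated with r = 0.989.

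Alternatives were a replicate block, only the 6 arrays compared, an intensity trend with a robust prior, array weights, quantile normalization, centring on the median, leaving out the dimmest 40%, a minimum log2 change of 1, a threshold of 0.01, an ordinary test and leaving out each array. A pseudocount of 1 or 32 and scaling to the hybridisation controls were added after the data had been seen. The sources used here gave no batch, scan date or culture for an array.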

Results

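The data came from liquid cultures of Arabidopsis Col-0 seedlings that had been kept in the dark for 24 h and then received 10 µM oligomycin, an inhibitor of the mitochondrial ATP synthase, or the same volume of ethanol. Each of the 4 groups (ethanol or oligomycin, harvested after 1 h or 4 h) held 3 biological replicates, so 12 arrays were compared, and 3 arrays per group limited the precision. The questions were which transcripts differed between oligomycin and ethanol at each time, whether the difference itself changed from 1 h to 4 h, and what changed in ethanol alone over the same hours. Values are array intensities given as mean ± SD (n = 3). Changes are on the scale of log2(intensity + 16), which understates the change of dim genes, and "rose" or "fell" is used only where the limma adjusted p was under 0.05.

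After 1 h of oligomycin, 11 of 12 measured genes of the mitochondrial dysfunction response and 5 of 11 measured detoxification genes had risen over the ethanol cultures. These lists had been written with 27 and 38 genes, and counts of list members here are of measured genes only. AT5G43450, which encodes a protein like 2-oxoglutarate-dependent dioxygenases, rose from 48.8 ± 16.1 to 624 ± 140.2 (log2 change 3.31, adjusted p = 6.57e-07). GSTU22 and GSTU25, glutathione transferases, rose from 65.5 ± 15.4 to 644 ± 95.4 and from 86.4 ± 16.2 to 509.8 ± 69.6. BZIP60, a transcription factor of the unfolded protein response, rose from 178 ± 23.0 to 643 ± 55.7, and ATG8E, a ubiquitin-like protein of the autophagosome, from 146 ± 29.0 to 686 ± 117. Falls were smaller, with a median log2 change of −0.53 against 0.85 for rises. They were also dimmer by the mean intensity over all 12 arrays (median 48.7 against 166). That mean includes the oligomycin arrays, so rises raise it and falls lower it. The scale understates the change of dim probe sets, but whether falls started dimmer in ethanol was not tested. Of the falls, sks15, a member of the SKU5-similar family, went from 212 ± 32.1 to 69.9 ± 6.57, and UGT72E2, a glucosyltransferase of monolignols, from 286 ± 54.9 to 138 ± 8.51.

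Of 22746 probe sets tested at 1 h, limma called 783 (523 rises and 260 falls), with 266 genes up and 147 down among probe sets that carried a single gene name. A log2 change of at least 1 was reached by 193 rises and 11 falls. Besides AT5G43450 and GSTU22, the largest named rises were AT2G41730 (3.94, from a probe set ending in _x_at, and such probe sets, like those ending in _s_at, can detect more than 1 transcript), AT2G32020 (3.65, an acetyltransferase-like protein), AT5G42830 (3.51, an acyltransferase-like protein) and AT3G54520 (3.33). AT4G28460, AT5G14730, AT5G40690 and AT2G23270 followed, between 2.89 and 3.03. Among the falls were sks16 (−1.28), AT2G43880 (−1.09, a polygalacturonase-like protein), AT4G25250 (−1.04, a pectin methylesterase inhibitor-like protein, not called with array weights), AT1G57590 (−1.01), AT3G21680 (−0.98), AT2G22930 (−0.94), AT1G14960 (−0.93) and AT3G19430 (−0.90). With every array centred on its median the share of falls at 1 h was 22.8% in place of 33.2%. With an ordinary equal-variance test on each probe set 22 were called in place of 783, and with only the 6 arrays of this time in the fit 441. Without the third oligomycin replicate of 1 h 343 rises and 98 falls were called, and without the first ethanol replicate 389 and 132.

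Gene lists were fixed before the data were examined, except that the organelle lists had to be matched another way once the tables had been read, and 25 of them held at least 3 measured genes. Some genes stand in more than 1 list, so the lists are not independent. NDB2 and NDB4 (alternative respiration), GSTU25 and AT2G04050 (detoxification) and AT5G51440 (heat shock) are also members of the mitochondrial dysfunction list. At 1 h camera called 7 lists, all upward, and 2 of these held with an estimated correlation. Other splits of the same 6 arrays into 3 and 3 gave up to 11 lists, so the number of lists alone does not show an effect. In the mitochondrial dysfunction list 11 of 12 members rose (11 also when adjusted over the list alone), with a median log2 change of 1.04 (adjusted p = 1.59e-29, and adjusted p = 0.0196 with an estimated correlation). Glutathione transferases and xenobiotic detoxification had 5 of 11 members up and none down (adjusted over the list alone, 6 up and 2 down), median 0.34, with adjusted p = 1.6e-08 and adjusted p = 0.0476 with an estimated correlation. Its risers included UGT73B5 and UGT73B4, glucosyltransferases (2.00 and 1.88), and the MATE transporter AT2G04050 (1.33).

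In the dark and sugar starvation list 5 of 9 members rose (adjusted over the list alone, 5 up and 1 down). They included MCCA and IVD of leucine breakdown (0.86 and 0.74), AT3G15450 (757 ± 97.9 to 1431 ± 72.7) and AKINBETA1, a subunit of the SnRK1 kinase (0.46). The list median was 0.46 (adjusted p = 2.15e-05, but adjusted p = 0.074 with an estimated correlation). WRKY6 was the only 1 of 7 members of the rapid touch, wound and elicitor list that rose (0.91), while 4 rose adjusted over the list alone. Its median was 0.39 (adjusted p = 2.15e-05, but adjusted p = 0.0557 with an estimated correlation). Of the 5 genes for alternative respiration, NDB2 and NDB4, external NADH dehydrogenases of mitochondria, rose (76.3 ± 14.7 to 144 ± 16.7 for NDB2, log2 change 0.57 for NDB4), as they did adjusted over the list alone. This list's median was 0.30 (adjusted p = 0.00381, but adjusted p = 0.0557 with an estimated correlation). The gene names used here assigned no probe set to AOX1A alone, so it was not analysed. This does not show that the array lacks it.

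The autophagy and mitochondrial genome lists were called with 1 riser each, also when adjusted over the list alone. For autophagy ATG8E alone rose among 9 members (median 0.07, adjusted p = 0.0361, but adjusted p = 0.729 with an estimated correlation). From the mitochondrial genome nad1 alone rose among 11 (28.7 ± 3.89 to 58.6 ± 1.62, list median 0.08, adjusted p = 0.0361, but adjusted p = 0.473 with an estimated correlation). Under scaling to the hybridisation controls the autophagy median was −0.02 and the mitochondrial genome median 0.017. With a pseudocount of 1 the 1 h medians were 1.57 for mitochondrial dysfunction, 0.58 for touch, wound and elicitor genes and 0.53 for alternative respiration.

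The machinery of respiration itself did not pass the test at 1 h. No member was called among 8 ATP synthase subunits (median −0.05), 17 complex I subunits (0.03), 19 subunits of complexes II to IV and cytochrome c (−0.05, with a mean of −0.02 and camera pointing upward) or 14 genes of the tricarboxylic acid cycle (−0.09). AT5G47030, the delta subunit of the ATP synthase, stood at 1141 ± 144 in ethanol and 1142 ± 16.4 in oligomycin. In glycolysis 2 of 8 members rose, both also when adjusted over the list alone: pyruvate kinase AT5G56350 (0.55) and AT1G76550 (0.54), a subunit of pyrophosphate-dependent phosphofructokinase, the latter not called with array weights. Lactate dehydrogenase AT4G17260 was the only riser of 17 in the hypoxia list (153 ± 35.0 to 415 ± 42.7). One heat shock list member of 8 rose, the mitochondrial small heat shock protein AT5G51440 (0.99).

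Members of the endoplasmic reticulum list moved apart at 1 h. BZIP60 rose (1.77) whereas the calreticulin CRT1b fell from 779.8 ± 12.3 to 550.3 ± 31.3 (1 up and 1 down of 4, and 1 up and 2 down adjusted over the list alone). The list's median was −0.25 while its mean was 0.19, and camera pointed downward without a call (adjusted p = 0.881). For auxin 2 of 8 genes rose when adjusted over the list alone and none over all probe sets. No member was called in the lists for abscisic acid and dehydration (4 genes), nuclear photosynthesis genes (5), cytosolic ribosomal proteins (3), ribosome biogenesis (10), expansins and xyloglucan endotransglucosylases (8), the cell cycle (3), the 26S proteasome (5), root markers (3) and the chloroplast genome (69). The medians of these 9 lists lay between −0.14 and 0.10, and none was called by camera, which pointed upward for the expansin list (median −0.05, mean −0.04) and for the dehydration list (median −0.01, mean 0.04). GRX480, a glutaredoxin of the salicylate response, rose from 25.3 ± 13.1 to 80.0 ± 6.60.

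Several named calls at 1 h did not hold when 1 array was left out, which also leaves fewer arrays for the test. Leaving out 1 of the 6 arrays of 1 h ended the calls of AT4G25250, AT1G76550 and AT5G51440 for 5 of the arrays, of AT5G56350 for 4, of WRKY6 for 2 and of CRT1b, IVD, AT2G22930 and AT1G14960 for 1.

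After 4 h of oligomycin all 12 measured mitochondrial dysfunction genes had risen, while of the 11 measured detoxification genes 7 had risen and 3 had fallen. AT5G43450 stood at 2266 ± 344 against 75.0 ± 7.63 in ethanol (log2 change 4.64, adjusted p = 3.47e-09), and GSTU25 at 2736 ± 143 against 115 ± 14.6. NDB2 had reached 722 ± 19.3 against 83.1 ± 15.4. SBT3.5, a subtilase, rose from 24.7 ± 6.31 to 1499 ± 82.0, and AT1G26380, a berberine bridge enzyme-like protein, from 25.6 ± 8.32 to 1364 ± 37.4. In the other direction AT1G14960, a protein like the major latex proteins, fell from 479.7 ± 36.2 to 63.4 ± 20.3, and DRT100, a leucine-rich repeat protein, from 481 ± 46.1 to 113 ± 16.3.

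Limma called 8345 of 22746 probe sets at 4 h (36.7%), 2594 up and 5751 down, which came to 1355 genes up and 3037 down. Counts of called list members are to be read beside this share. Rises were fewer and larger: 1082 rises and 605 falls reached a log2 change of at least 1, and the median change was 0.84 among rises and −0.56 among falls. The share of falls depended on the scaling. It was 68.9% with the deposited values, 60.7% after quantile normalization, 61.1% after scaling to the hybridisation controls and 47.1% with arrays centred on their medians, a step that moved the median change of all probe sets from −0.099 to 0.062. On the log2(intensity + 16) scale, which sets the order of genes that are dim in ethanol, AT2G20720 had the largest named rise (17.1 ± 12.2 to 2152 ± 213, log2 change 6.10). Other large rises, besides those of SBT3.5 (5.23) and AT1G26380 (5.07), were AT3G54520 (5.66), AT4G28460 (5.49), AT5G42830 (5.01), AT4G39670 (4.97), AT1G74870 (4.87) and AT2G23270 (4.84). Besides DRT100 (−1.95), the largest named falls after AT1G14960 (−2.68) were AT4G22610 (−2.15), AT5G46230 (−2.11), AT3G54400 (−2.11, an aspartyl protease-like protein), AT1G29660 (−2.10, a GDSL lipase-like protein), AT2G41800 (−2.05), GSTU26 (−1.99), AT1G20070 (−1.97) and AT5G20700 (−1.95).

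**Figure D1:**
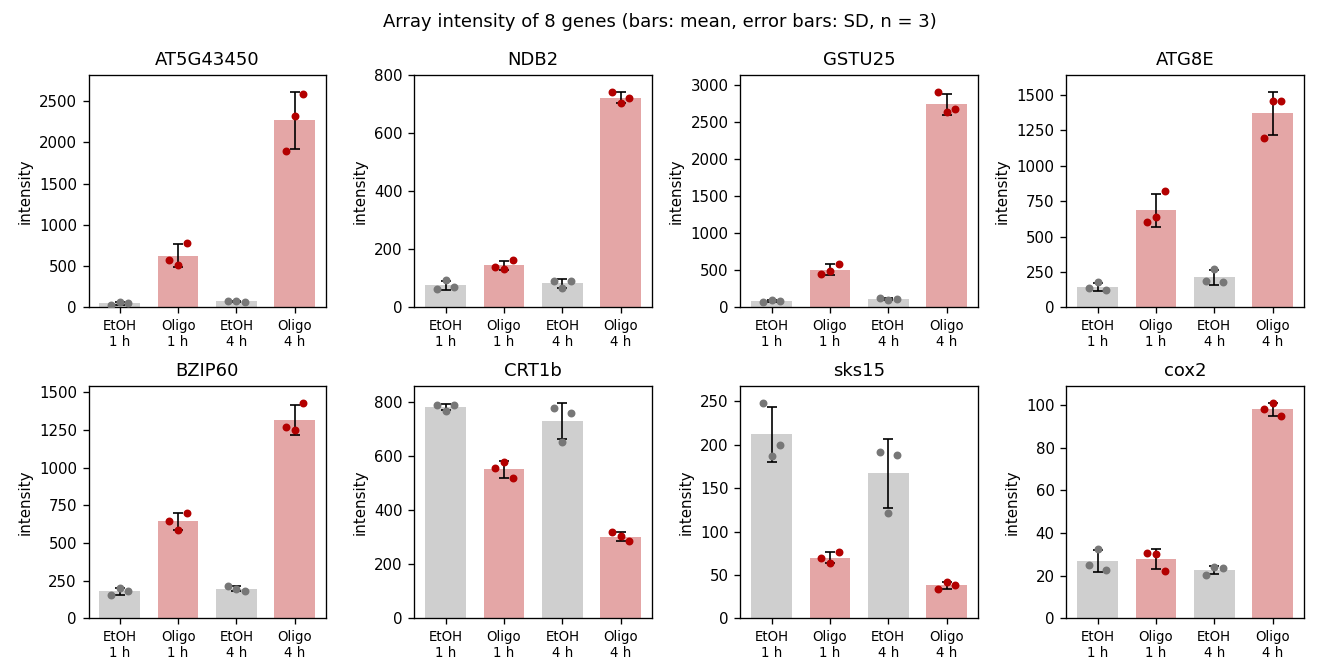
Array intensity (linear axis from 0) of 8 genes in ethanol and oligomycin cultures at 1 h and 4 h, with points for the arrays, bars for the mean and error bars for the SD (n = 3). AT5G43450, NDB2, GSTU25, ATG8E and BZIP60 stand above ethanol at both times, CRT1b and sks15 below it, and cox2 reached 98.0 ± 3.01 against 22.6 ± 1.87 at 4 h.

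Camera called 8 lists at 4 h, all upward, and 2 of them held with an estimated correlation. Other splits of the same 6 arrays gave up to 7 lists. All 12 members of the mitochondrial dysfunction list rose, also when adjusted over the list alone (median 3.17, adjusted p = 2.57e-21, and adjusted p = 0.0271 with an estimated correlation). The MATE transporters AT2G04070 and AT2G04050 were among them (4.50 and 4.26). All 7 members of the touch, wound and elicitor list rose, also when adjusted over the list alone: the transcription factors WRKY6 (47.9 ± 4.14 to 303 ± 64.0) and WRKY53 (1.90), the zinc finger protein STZ (1.89), the calmodulin-like CML37 (1.63) and 3 plant U-box ubiquitin ligases. That list's median was 1.63 (adjusted p = 2.15e-08, and adjusted p = 0.0271 with an estimated correlation).

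Detoxification genes split by member. In this list 7 of 11 rose and 3 fell, over all probe sets as adjusted over the list alone, with a median of 1.56 (adjusted p = 0.000286, but adjusted p = 0.139 with an estimated correlation). With a pseudocount of 1 that median was 3.89. GSTU25, GSTU22 (4.23), UGT73B4 (4.00) and UGT73B5 (3.54) were up, while GSTU26, which lies next to GSTU25, dropped from 222 ± 58.9 to 42.8 ± 1.89 and GSTU20 by 1.11 on the log2 scale. For dark and sugar starvation 5 of 9 rose and 2 fell (6 and 2 adjusted over the list alone). MCCA (1.72), AT3G15450 (1.41), IVD (1.21) and ETFQO (0.97), which passes electrons from amino acid breakdown to ubiquinone, were up. The list median was 0.97 (adjusted p = 0.00169, but adjusted p = 0.193 with an estimated correlation). Alternative respiration had NDB2 (2.91), NDB4 (2.28) and NDB3 (0.42) up and NDC1 down (−0.33) among 5 members, the same 3 and 1 adjusted over the list alone. Its median was 0.42 (adjusted p = 0.0121, but adjusted p = 0.108 with an estimated correlation). Of 9 autophagy genes ATG8E (2.62), ATG8H (1.12) and APG8A (0.41, not called after quantile normalization) rose, also when adjusted over the list alone (median 0.25, adjusted p = 0.0138, but adjusted p = 0.586 with an estimated correlation).

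Of 11 transcripts of the mitochondrial genome, with mean intensities over all arrays from 3.78 to 98.7, 9 rose at 4 h, also when adjusted over the list alone, with a median of 0.77 (adjusted p = 4.25e-07, but adjusted p = 0.0625 with an estimated correlation). Examples were cox2, a subunit of cytochrome c oxidase (1.56), nad1 (1.39), nad6 (13.2 ± 4.14 to 80.8 ± 8.54) and nad5 (39.4 ± 4.12 to 117 ± 8.32), subunits of complex I, the last pair read by _s_at probe sets. The chloroplast genome list was also called upward, with a small median of 0.18 over 69 genes (adjusted p = 0.000286, but adjusted p = 0.467 with an estimated correlation). With arrays centred on their medians it was 0.35, and those of autophagy, glycolysis and heat shock genes were 0.41, 0.31 and 0.47. Of the 69 chloroplast genes 8 rose and 1 fell, and none passed adjusted over the list alone. The control probe set for 25S ribosomal RNA stood at 1677 ± 125 in ethanol and 2440.0 ± 46.4 in oligomycin at the same time (exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays allow). Of the chloroplast genes ndhF (0.71), petD (0.58) and psaA (0.53) had the largest rises. The first pair was dim, below the added 16 in ethanol: 5.1 ± 3.99 to 18.8 ± 7.36 for ndhF and 11.97 ± 5.38 to 25.77 ± 8.1 for petD.

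Few nuclear genes of the respiratory chain were called at 4 h. Of 8 ATP synthase subunits 2 fell (1 adjusted over the list alone), AT4G26210 by 0.44 and AT5G47030 by 0.30 on the log2 scale, with a list median of −0.19 (camera adjusted p = 0.489). Of 17 complex I subunits 3 fell (1 adjusted over the list alone), by up to 0.48 for AT3G06310 (median −0.12, adjusted p = 0.693). In complexes II to IV 3 of 19 fell and 1 rose (2 and 0 adjusted over the list alone), among them MPPBETA (−0.35), cytochrome c1 AT3G27240 (−0.34) and the riser AT5G25450 (0.43, not called after quantile normalization), with a median of −0.10 (adjusted p = 0.869). For the tricarboxylic acid cycle 4 of 14 fell and 1 rose, also adjusted over the list alone (median −0.08, adjusted p = 0.751). The riser AT4G26910 encodes an E2 subunit of 2-oxoglutarate dehydrogenase (0.85), and the falls included AT1G54220 and AT3G13930, E2 subunits of pyruvate dehydrogenase (−0.57 and −0.46). With arrays centred on their medians the list medians were −0.03 for the ATP synthase and above 0 for complex I (0.04), complexes II to IV (0.06) and this cycle (0.09). Fry called all 4 lists downward, with adjusted p = 0.00348 for the ATP synthase, 0.00354 for complex I, 0.0108 for complexes II to IV and 0.0451 for the cycle. It tests a list by itself, while the median change of all probe sets at 4 h was −0.099. The fry calls therefore do not show that these lists fell beyond other genes. After quantile normalization camera also called the ATP synthase list downward.

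Glycolysis and hypoxia genes went both ways at 4 h. Pyruvate kinase AT5G56350 (386 ± 21.7 to 1124 ± 182) and triosephosphate isomerase TPI (0.49) were among 4 risers of 8 in glycolysis, with 2 falls (4 and 2 adjusted over the list alone, median 0.15, adjusted p = 0.232). Phosphofructokinase subunits parted, with AT1G76550 at 1.06 and AT1G20950 at −0.79. In the hypoxia list 2 of 17 rose and 6 fell, also adjusted over the list alone (median −0.58, adjusted p = 0.51). Lactate dehydrogenase AT4G17260 rose from 183 ± 48.1 to 1460.0 ± 62.8 while AT5G66985 (−1.52), AT3G27220 (−1.34) and AT4G33560 (−1.31) fell.

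Genes for protein folding parted further. CRT1b (728 ± 66.8 to 302 ± 17.1), ATERDJ3B (−0.96) and DER1 (−0.58) fell while BZIP60 rose to 1316 ± 99.8 (1 up and 3 down of 4, also adjusted over the list alone, median −0.77, mean −0.03, adjusted p = 0.509). Of 8 heat shock genes AT5G51440 (2.18) and AT5G37670 (1.25) rose, also adjusted over the list alone (median 0.31, adjusted p = 0.0881).

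Of the growth and photosynthesis lists camera called none. Fry, which tests a list by itself and not against the other genes, called 18 lists at 4 h, among them downward ribosome biogenesis (adjusted p = 0.00249), cytosolic ribosomal proteins (adjusted p = 0.00438), nuclear photosynthesis genes (adjusted p = 0.00859) and expansins (adjusted p = 0.0299). Expansins and xyloglucan endotransglucosylases had 5 falls and 2 rises of 8, also adjusted over the list alone (median −0.62, adjusted p = 0.667). EXPA8 fell from 57.1 ± 8.50 to 11.6 ± 3.97 and EXPA15 by 1.09 on the log2 scale, whereas XTH18 rose from 218 ± 48.8 to 1193 ± 142. Nuclear photosynthesis genes had 3 falls of 5 (4 adjusted over the list alone, median −0.38, adjusted p = 0.192): LHCB4.2 (−0.67), PSAE-1 (−0.47) and PSAN (−0.38). In ribosome biogenesis 4 of 10 fell, also adjusted over the list alone (median −0.26, adjusted p = 0.192), with AT3G15460 (−0.85) and the RNA helicase PRH75 (−0.69) in front. Of 3 cytosolic ribosomal protein genes AT3G09630 fell (−0.35, 2 falls adjusted over the list alone, median −0.27, adjusted p = 0.395). With arrays centred on their medians the list medians were −0.22 for photosynthesis, −0.10 for ribosome biogenesis and −0.11 for ribosomal proteins, and after quantile normalization camera called photosynthesis genes and ribosome biogenesis downward.

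Smaller groups gave single changes at 4 h. Limma called 36.7% of all tested probe sets then (2594 up and 5751 down of 22746), so single calls in a list are not a result about it. Of 4 dehydration genes the dehydrins LTI30 and COR47 went apart (2.05 and −1.19, median 0.01, adjusted p = 0.667). Of 8 auxin genes WES1 rose (0.62) and LBD29 fell (−0.58), with a median of −0.09, a mean of −0.01 and camera pointing upward (adjusted p = 0.693). PRL fell among 3 cell cycle genes (−0.41, not called after quantile normalization, median −0.31, adjusted p = 0.511), EXPA18 among 3 root markers (−0.61, median −0.57, adjusted p = 0.688), and AT2G32730 and AT5G45620 among 5 proteasome genes (−0.38 and −0.33, median −0.13, adjusted p = 0.751). With arrays centred on their medians the auxin and proteasome medians were 0.07 and 0.03, and that of the cell cycle list was −0.15. A pseudocount of 1 gave a root marker median of −1.04. Outside the tested lists BCAT4 and UGT74B1 of glucosinolate synthesis fell (−1.74 and −0.61), the clock gene GI fell (−0.64), and GRX480 and SAG101 of the salicylate response rose (2.07 and 1.27). JMT and PRXIIF were not called (0.07 and −0.14).

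Several small changes at 4 h also lost their call when 1 array was left out, which leaves fewer arrays for the test. Leaving out 1 of the 6 arrays of 4 h ended the calls of NDB3, AT5G47030, APG8A, AT5G45620 and the complex I subunit AT4G16450 for 5 of the arrays. It ended those of AT5G25450, PSAE-1, PSAN, WES1, LBD29, ndhF and the complex I subunit AT5G52840 for 4, of PRL, AT3G27240 and psaA for 3 and of petD for 2.

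**Figure D2:**
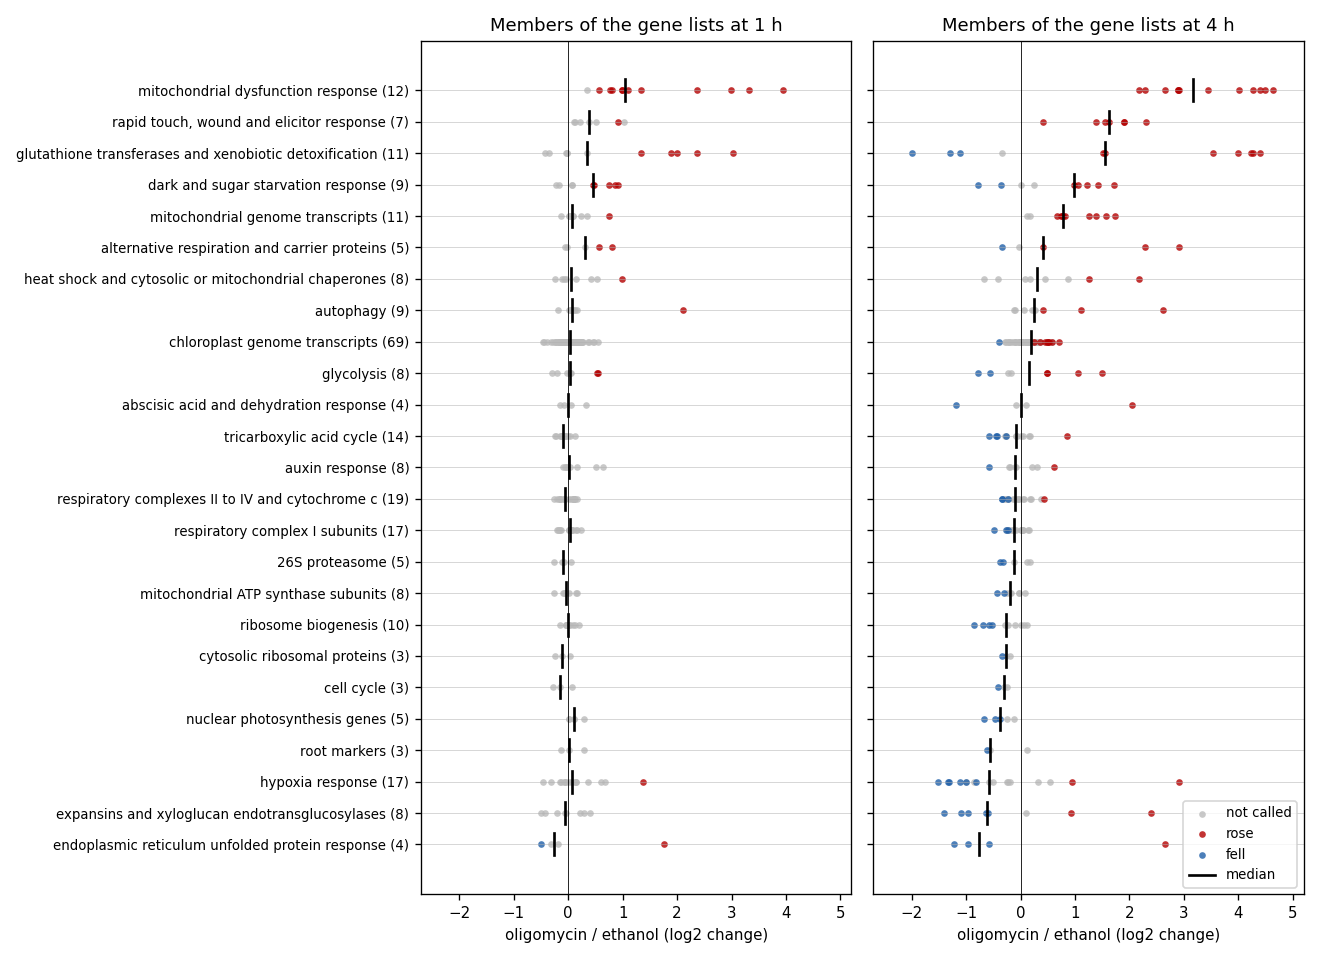
Log2 change of oligomycin over ethanol (horizontal axis) for each measured member of the 25 tested gene lists (vertical axis, number of members in brackets) at 1 h and 4 h. Points are genes, coloured by the limma call, and the vertical bar is the list's median, which for the mitochondrial dysfunction response lies at 1.04 at 1 h and 3.17 at 4 h.

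The response of 1 h was largely kept at 4 h. Of the 523 rises at 1 h, 478 were also rises at 4 h (91.4%), where independent calls would share 59.6 probe sets. Of the 260 falls, 185 were also falls (71.2%), where independent calls would share 65.7 probe sets. Among the 1 h rises 84.1% were larger at 4 h, with a median ratio of 1.87 between the log2 changes, and among the falls 53.8% were larger. ATG8E had log2 changes of 2.12 and 2.62 at the 2 times (interaction adjusted p = 0.201) and AT2G41730 of 3.94 and 4.01 (interaction adjusted p = 0.922), whereas GSTU25 went from 2.36 to 4.39 (interaction adjusted p = 2.01e-05). Over all probe sets, which are not independent replicates, the log2 changes at the 2 times correlated with r = 0.593. In 46.8% of probe sets the 3 oligomycin arrays lay wholly above or below the 3 ethanol arrays at 4 h, and in 19.8% at 1 h, where chance gives 10%.

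**Figure D3:**
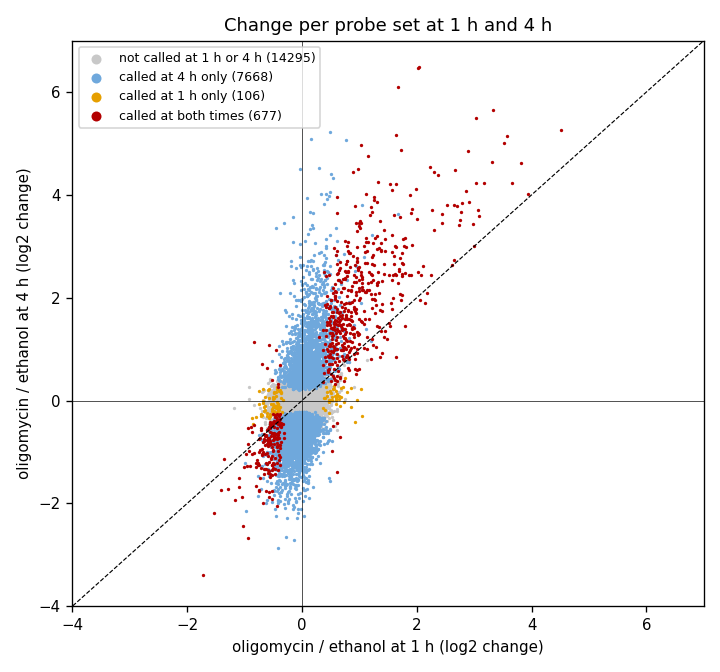
Log2 change of oligomycin over ethanol at 4 h (vertical axis) against 1 h (horizontal axis) for 22746 probe sets, coloured by the limma calls at each time, with the line of equal change dashed. Of the 523 rises called at 1 h, 84.1% lie above the line.

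The oligomycin effect itself differed between the times for many genes. SBT3.5 stood at 26.8 ± 6.67 and 43.6 ± 7.01 at 1 h in ethanol and oligomycin but had risen at 4 h, so that the difference between the log2 changes was 4.75 (limma interaction, adjusted p = 9.65e-08). AT1G57630, a protein with a TIR domain, behaved alike (2.37 ± 2.08 and 1.90 ± 0.36 at 1 h, 1.90 ± 0.56 and 393 ± 66.8 at 4 h, interaction 4.53), as did AT2G20720 (4.44), AT1G26380 (4.30) and its neighbour AT1G26390 (4.23). AT2G28080 reversed, with a rise from 178 ± 18.7 to 279 ± 19.1 at 1 h and a fall from 263 ± 44.8 to 91.0 ± 19.3 at 4 h (interaction −1.99). AT3G54400 (−2.05), AT5G28500 (−1.97), AT1G29660 (−1.95) and AT5G20700 (−1.86) had the other largest negative differences.

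In all, limma called 4043 of 22746 probe sets for this interaction, 1637 more positive and 2406 more negative at 4 h (844 and 1173 genes). The share of negative differences was 59.5% with the deposited values, 51.7% after quantile normalization, 40.8% with arrays centred on their medians and 34.7% after scaling to the hybridisation controls, under which 2388 probe sets were called. Camera called 8 lists, none of them with an estimated correlation. Upward were mitochondrial dysfunction (10 of 12 members called up, median 1.84, adjusted p = 2.13e-14, but adjusted p = 0.0823 with an estimated correlation) and touch, wound and elicitor genes (5 of 7, median 1.26, adjusted p = 2.08e-06, but adjusted p = 0.0823 with an estimated correlation). Mitochondrial genome transcripts (6 of 11, median 0.75, adjusted p = 2.25e-05, but adjusted p = 0.13 with an estimated correlation) and detoxification genes (7 up and 3 down of 11, median 1.21, adjusted p = 0.00714, but adjusted p = 0.315 with an estimated correlation) were also upward. Alternative respiration (2 of 5, median 0.12, adjusted p = 0.0401, but adjusted p = 0.186 with an estimated correlation) and the chloroplast genome (median 0.11, adjusted p = 0.0392, but adjusted p = 0.682 with an estimated correlation) completed the upward lists. The chloroplast median was 0.225 with arrays centred on their medians and 0.219 after scaling to the hybridisation controls. Downward were nuclear photosynthesis genes (1 of 5, median −0.40, adjusted p = 0.0432, but adjusted p = 0.536 with an estimated correlation) and ribosome biogenesis (3 of 10, median −0.38, adjusted p = 0.0471, but adjusted p = 0.536 with an estimated correlation).

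Few probe sets were called between 1 h and 4 h in ethanol alone. AT5G57760 fell from 137 ± 38.8 to 38.0 ± 2.87 (log2 change −1.47, adjusted p = 0.00749), and the only other called probe set, also a fall, had no single gene name here. Limma called 2 of 22746 probe sets, with 2712 at an unadjusted p under 0.05. The count was 133 without the second ethanol replicate of 1 h, the array with the lowest correlations to its group. Without the third ethanol replicate of 1 h or the first of 4 h the count was 0, so that AT5G57760 was not called.

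Camera called 8 lists for time in ethanol, without a single member called over all probe sets and none of them with an estimated correlation. Another split of the same 6 arrays also gave 8 lists, so this number does not show an effect of time. The heat shock list (median 0.82, adjusted p = 6.41e-07, but adjusted p = 0.295 with an estimated correlation), with 6 of 8 members up adjusted over the list alone, and the hypoxia list (median 0.41, adjusted p = 2.98e-07, but adjusted p = 0.383 with an estimated correlation) were higher at 4 h. AT2G29500, a small heat shock protein, stood at 216 ± 178 at 1 h and 389.6 ± 139 at 4 h. Mitochondrial dysfunction (median 0.32, 6 of 12 members up adjusted over the list alone, adjusted p = 3.11e-07, but adjusted p = 0.295 with an estimated correlation), starvation (0.15, adjusted p = 0.000853, but adjusted p = 0.295 with an estimated correlation), detoxification (0.10, adjusted p = 0.0107, but adjusted p = 0.335 with an estimated correlation) and autophagy (0.06, adjusted p = 0.0397, but adjusted p = 0.603 with an estimated correlation) were called in the same direction. Lower at 4 h were the chloroplast genome (−0.24, adjusted p = 1.58e-08, but adjusted p = 0.295 with an estimated correlation) and the expansin list (−0.20, adjusted p = 0.0397, but adjusted p = 0.295 with an estimated correlation).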

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

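Tests chosen only after the result was seen were those of scaling and RNA degradation behind the falls at 4 h, and those of scaling and of RNA without long poly(A) tails behind the mitochondrial transcripts, and how the overlap splits, RNA degradation and poly(A) tests were read was also settled after their values were seen.

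Results were flagged here because the oligomycin effect differed between 1 h and 4 h in the interaction test. The limma count was 4043 probe sets. Of 100 drawn splits that exchanged the times within each treatment, 6 gave a count as large, with 6181 as the highest other. All 6 were among the 7 splits that kept the 3 oligomycin arrays of each time together, and the splits that did not had at most 0 calls. Few probe sets were called with time in ethanol, so the 7 splits nearly repeat the real contrast. That scheme therefore could not decide whether chance gives the probe set count. For the 8 lists called, 8 of 100 splits gave as many, the highest other 10. Some of these splits had 0 probe sets called, so chance was not excluded for the number of lists.

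Median interactions of those lists were 1.84 for mitochondrial dysfunction, 1.26 for touch, wound and elicitor genes, 1.21 for detoxification, 0.75 for mitochondrial genome transcripts, 0.12 for alternative respiration, 0.11 for the chloroplast genome, −0.40 for nuclear photosynthesis genes and −0.38 for ribosome biogenesis. Single genes flagged for the same reason were SBT3.5 (4.75), AT1G57630 (4.53), AT2G20720 (4.44), AT1G26380 (4.30), AT1G26390 (4.23), AT3G54400 (−2.05), AT2G28080 (−1.99), AT5G28500 (−1.97), AT1G29660 (−1.95) and AT5G20700 (−1.86).

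Some control probe sets outside the comparisons stood above the ethanol arrays at 4 h and were flagged for a signal in values outside the main measurement. The means in oligomycin were 2440.0 for 25S ribosomal RNA (ratio 1.45), 3748.73 for the 3' probe set of GAPDH (1.61) and 3219.5 for that of ubiquitin (1.21), each with an exact two-sided permutation p of 0.1 and an adjusted p of 0.267 over 16 tests. The 3' probe set of actin stood lower in oligomycin, at 1568 against 2068 (ratio 0.758), with the same p and adjusted p.

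Counts of the main comparisons were set against other splits of the same 6 arrays. There are only 10 splits with the real one, too few to exclude chance by a share under 0.05. At 1 h 783 probe sets were called against a highest other of 0 (1 split as large, the real one), and 7 lists against a highest other of 11 (3 splits). At 4 h the values were 8345 against 0 (1 split) and 8 lists against 7 (1 split), and for time in ethanol 2 against 1 (1 split) and 8 lists against 8 (2 splits). For the list counts at 1 h and for time in ethanol, other splits gave as many or more, so chance can give those counts. For the 663 probe sets called at both times in the same direction, 1 of 100 drawn splits, the real one, gave as many and the highest other was 0. Every other split at 1 h or 4 h called 0 probe sets, so an overlap of 0 was bound to follow, and that count did not test chance in the overlap.

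Falls outnumbered rises at 4 h (68.9% of calls). The scaling of every array to one trimmed mean could account for that excess: over other scalings the share of falls went as low as 47.1%, and no value decided which scaling is right. More degraded RNA in the oligomycin arrays stays open: the mean log2 3'/5' ratio of 3 control genes differed by 0.0128 (standard error 0.0128), but the genes went both ways, with ratios of oligomycin to ethanol of 1.11 for actin, 0.946 for GAPDH and 0.982 for ubiquitin. No biological explanation was tested.

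Of 11 transcripts of the mitochondrial genome 9 rose at 4 h (median 0.77, with the list's call lost at adjusted p = 0.0625 with an estimated correlation). Scaling was argued against by a lowest median of 0.824 over other scalings, and dim probe sets by the list's percentile of 100 among random lists matched on intensity. A common rise of RNA without long poly(A) tails stays open: the mitochondrial median lay 0.590 above the chloroplast one (permutation over genes, which are not independent replicates, p = 1e-05), but 25S ribosomal RNA stood 1.45 times higher and the chloroplast list was itself called upward. Nuclear copies of the mitochondrial genome, a change in polyadenylation and a biological rise were not tested.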

How the results depend on the processing

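Alternatives chosen only after the data were seen were the pseudocounts of 1 and 32, scaling to the hybridisation controls, the matching of organelle lists and the split of simulated recovery by intensity. No named gene that was called changed sign with the replicate block, array weights, quantile normalization or 1 array left out, and the cause of the shifts was not tested unless named. The balance of calls did turn with the scaling: with arrays centred on their medians 3844 rises and 3423 falls were called at 4 h in place of 2594 and 5751, and 2171 positive and 1497 negative interactions in place of 1637 and 2406, or 1559 and 829 after scaling to the hybridisation controls. List medians turned from negative to positive with median centring at 4 h for complex I, complexes II to IV, the tricarboxylic acid cycle, the proteasome and auxin. Under hybridisation scaling those at 1 h turned negative for complex I, glycolysis, hypoxia, ribosome biogenesis, auxin, autophagy, root markers and the chloroplast genome, all from 0.07 or less. Only 6 arrays and the ordinary test were planned as not for the interaction and were not run there. Signal over background limits dim probe sets: on simulated data a log2 change of 1 at 1 h was recovered in 80.8% of 26 among the dimmest 40% and in 97.6% of 41 others, with median standard deviations within groups of 0.18 and 0.15. These counts are small, and for time in ethanol a change of 0.5 was recovered more often among the dimmest (46.7% against 35.1%).

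With a replicate block the counts were 750 at 1 h, 8278 at 4 h, 3901 for the interaction, 638 at both times and 1 in place of 2 for time in ethanol. Replicate numbers of the labels did not pair arrays: same-number correlations ran from −0.091 to 0.167, with 3 of 18 over 0.1, and 5 of 12 arrays matched best with their own number.

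With only the 6 arrays compared, which leaves fewer arrays for the spread, 441 were called at 1 h, 0 for time and 399 at both times. The ordinary test gave 22, 0 and 20. Requiring a log2 change of at least 1, which is stricter by construction, left 204 at 1 h, 1687 at 4 h, 1148 for the interaction, 1 for time and 198 at both times, and a threshold of 0.01 left 389 at 1 h, 2197 for the interaction, 1 for time and 365 at both. The pseudocount of 1 gave 513 at 1 h and 1 for time. Scaling to hybridisation controls gave 2388 for the interaction and 1 for time, centring on medians 1 for time, an intensity trend 4, and leaving out the dimmest 40% 42. Without 1 array the ranges were 441 to 833 at 1 h, 7060 to 7715 at 4 h, 3227 to 4017 for the interaction, 0 to 133 for time and 402 to 718 at both times. Without the third oligomycin replicate of 1 h these were 441 at 1 h and 402 at both times, and without the first ethanol replicate of 1 h 521 at 1 h.

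Lists moved more. With an estimated correlation 2 were called at 1 h, 2 at 4 h, 0 for the interaction and 0 for time. Fry called 18 at 4 h and 0 for time, ranks 2 at 1 h and 5 at 4 h. Leaving out the dimmest 40% gave 4 at 1 h and 5 for the interaction, and a pseudocount of 1 gave 5 for the interaction. Without 1 array the ranges were 5 to 10 at 1 h, 8 to 9 at 4 h, 4 to 9 for the interaction and 5 to 8 for time. The lowest counts came without the third ethanol or the first oligomycin replicate of 1 h (4 for the interaction) and the first ethanol replicate of 1 h (5 for time).

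Log2 changes of named genes kept their side of the threshold in 173 values and lost it in 2 with array weights, in 168 and 7 after quantile normalization, in 172 and 3 with the replicate block (AT4G25250 at 1 h, AT4G16450 at 4 h and the interaction of AT5G42740), and in 1224 and 126 when 1 array was left out.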

Other observations

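Tests here were planned before their results were seen, apart from the choice of genes called in opposite directions at the 2 times, which was made after, and the reading of the test without _s_at or _x_at probe sets, whose bound had been set beforehand and was put aside once the number of pairs left out was seen.

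A few genes were called in opposite directions at 1 h and 4 h, 9 probe sets from a fall to a rise and 5 from a rise to a fall. AT3G13650, a dirigent-like protein, stood at 235 ± 52.1 in ethanol and 122 ± 9.97 in oligomycin at 1 h and at 233 ± 23.1 and 534 ± 44.7 at 4 h (log2 changes −0.84 and 1.15, interaction 1.99). SGP1, a small GTP-binding protein, went from −0.39 to 0.68. In the other direction the zinc finger protein AT2G28200 went from 0.55 to −0.50.

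The hypothesis that neighbours on a chromosome share part of the response was tested on 5814 adjacent measured pairs. Across genes, which are not independent replicates, the log2 changes at 4 h correlated with r = 0.151 (permutation p = 1e-04, highest shuffled 0.0592) and with 0.0358, 0.0441, 0.00974 and 0.0105 at 2, 5, 10 and 20 genes apart. Without probe sets ending in _s_at or _x_at r was 0.149, but the filter left out only 59 pairs, too few to decide, and other probe sets can also detect a similar neighbour, so detection of more than 1 transcript stays open. Of 797 pairs with both genes called 68.5% went the same way, against 57.7% if independent. Examples were AT1G26380 and AT1G26390 (5.07 and 4.52) and UGT73B5 and UGT73B4 (3.54 and 4.00), while GSTU25 and GSTU26 parted (4.39 and −1.99). The result could come from a shared response, but related genes lying side by side were not separated from unrelated ones. Over pairs where neither changed by 1 or more r was 0.0484, but choosing pairs by the size of the change can itself lower r. Of 51 pairs with both genes called and changed by at least 1, 44 went the same way.

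No family outside the fixed lists was called, in a test for a shift of a family in 1 direction. That test cannot see a response in which members go both ways, such as UGT at 4 h (8 up and 11 down of 43). Families were formed from the letters of the symbol before its first digit, which can pool different gene groups. Of 23 families named by a common symbol, with at least 8 members, camera called 0 at 4 h with the preset correlation, and 0 with an estimated one, the lowest adjusted p at the preset correlation being 0.305 for GH.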
